A study of Rattus norvegicus with 8 samples.

How the data were processed

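Total RNA from pooled trigeminal nerves of untreated 85-day-old rats was labelled with biotin and hybridised by the authors to Illumina RatRef-12 bead arrays, 1 array per strain and sex, and read with GenomeStudio 2010. The deposited non-normalized table holds the average bead signal of each probe as linear intensity, without background subtraction or scaling between arrays. The deposited detection p-values stand beside each signal, in steps of 0.00121, so that each probe was ranked against 825 background values. The value table of the authors also holds linear intensity. Tested on the values, each of its columns was a straight line of that array's non-normalized signal with a slope and an offset per array (largest residual 0.0143), and some values lay below 0. The names of the authors' background and scaling options are not stated.

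The non-normalized table was used for the main results. In R 4.3.3 with limma 3.58.1, neqc was run with an offset of 16: the background was modelled with negative controls inferred from the detection p-values, and log2 values were quantile normalized. Probes with a detection p under 0.05 on at least 2 of the 8 arrays were tested, 13114 of 22523, of which 9353 carried a gene symbol and covered 9154 genes. Of all probes 13793 had 1 symbol and 8730 had none, and 13752 were matched by gene identifier. The array names no genome build, so chromosomes and gene order were taken from the GRCr8 assembly by gene. For lists and chromosomes each gene was represented by its probe with the highest mean.

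Each probe was fitted in limma with strain and sex as terms over all 8 arrays, which leaves 3 residual degrees of freedom. The moderated variance had 4.09 prior degrees of freedom and a prior SD of 0.223, and the median residual SD was 0.217. The residual spread is the part of the sex difference that varies between strains plus array noise, since no strain had a replicate within a sex. The number of arrays limits the precision. An interaction of strain and sex has no residual degrees of freedom and was not tested. No paired analysis was possible because no label pairs individual pools beyond strain and sex, which are both terms of the fit. There were 5 comparisons, with a two-sided Benjamini-Hochberg adjusted p under 0.05 as threshold.

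Gene lists for cell types, tissues and pathways, 34 in all, were written before the data were examined, as were the comparisons, tests, thresholds, naming rule and the alternatives below, except where stated. Of these 32 had at least 3 tested genes and were tested with limma camera at a preset correlation of 0.01, adjusted over 160 tests, and again with an estimated correlation. Counts of members past the threshold are given over all genes and adjusted over the list alone. Chromosomes were compared with Fisher's exact test, two-sided and adjusted over 84 tests, and windows of 20 neighbouring genes with 1000 permutations of the calls. Direction against BDIV was compared with 100 simulations of unchanged groups that share the BDIX arrays. Within strains, male minus female values were set beside 10000 random lists matched on expression.

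Named genes followed a rule: per strain comparison the 10 largest rises and falls past the threshold with the same direction in both sexes, up to 4 members of each list that passed or had members past the threshold, and for sex the 5 smallest p-values each way. The 5 genes with the largest spread of male minus female over strains were added. Where a probe was not above background on both arrays of a strain, the fold is a lower bound, from the bright mean against the lowest detected value of each dim array or its own value if higher.

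Alternatives were no background correction, scaling of arrays to their medians, the authors' values, no filter, detection p under 0.01 on all 8 arrays, a trended robust variance, no moderation, no sex or strain term, only the 4 arrays of the 2 strains compared, chromosome calls at an unadjusted p under 0.001, and leaving out each array in turn. With an array left out, a strain with 1 array was assumed to vary like the others, with 2 residual degrees of freedom. Alternatives without both Mss4d arrays, without each strain in the sex lists, and without each array for the lists and chromosomes were added after seeing the data, as were 4 further gene lists. The fit was tested on simulated data with 200 changed probes: of differences of 1 on the log2 scale it recovered 0% between strains and 48% between sexes, and of differences of 2 between 87.5% and 98.5%, with 0 to 10 false calls. These rates hold for few changed probes, since the adjusted threshold is looser where more change. Of 2758 probes called in BDIV against BDIX, 1665 differed more than 2-fold, so smaller differences also passed.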

Results

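Gene expression was measured on 8 Illumina RatRef-12 bead arrays in untreated trigeminal nerve of 85-day-old rats. The 4 strains were BDIX, BDIV and the congenic strains BDIX.BDIV-Mss4a and BDIX.BDIV-Mss4d, shortened below to Mss4a and Mss4d, which carry a BDIV chromosome segment on the BDIX background. BDIX rats are known to develop malignant tumours of the trigeminal nerve after the carcinogen ethylnitrosourea, BDIV rats are resistant, and Mss4 names a locus tied to that difference. Each strain gave 1 pool of female and 1 pool of male nerves, so no strain had a replicate within a sex, and the number of animals per pool is not stated. The median bead signal was 145 and 141 in the Mss4d female and male arrays, 93.5 and 98.7 in Mss4a, 95.6 and 95.7 in BDIV, and 80.2 and 86.9 in BDIX. Between 47.7% and 54.3% of the 22523 probes were above background, and 13114 probes were tested. The number of arrays limits the precision of every value, and brightness differed by strain: the 75th percentile of signal was 209 and 215 in Mss4a against 485 and 484 in Mss4d, so strain and array batch cannot be separated in this design. The BDIV arrays correlated across tested probes with r = 0.996, the Mss4a arrays with 0.980, the Mss4d arrays with 0.979 and the BDIX arrays with 0.978, and the Mss4d female array correlated as highly with the BDIX male array (0.979). Genes are not independent replicates in these correlations. Differences below are log2 ± standard error from limma, with n = 2 arrays per strain. The p-values rest on the part of the sex difference that varies between strains plus array noise, pooled over all strains. The pairs were unequal: male minus female had an SD over 8241 probes of 0.200 in BDIV, 0.341 in Mss4a, 0.415 in Mss4d and 0.525 in BDIX. Pooling therefore lets the closer BDIV pair lower the standard errors of comparisons without BDIV.

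The comparison of BDIV with BDIX asks how the resistant and the susceptible strain differ before any exposure. Markers of sensory neurons and of mitochondrial respiration were higher in BDIV nerve, and markers of myelinating Schwann cells, fibroblasts, red cells and granulocytes were lower. Of 20 tested sensory neuron genes 10 rose and 0 fell (15 adjusted over the list alone; median 1.10; camera adjusted p = 5.25e-06). This list and the oxidative phosphorylation and myelinating Schwann cell lists each had adjusted p = 0.890 with an estimated correlation. The sensory neuron genes included the surface protein gene Thy1 (1.76 ± 0.30), the neuropeptide genes Gal (1.59 ± 0.27) and Calcb (1.51 ± 0.26), and the neuronal deubiquitinase gene Uchl1 (1.67 ± 0.29). Of 45 oxidative phosphorylation genes 15 rose and 0 fell (22 adjusted over the list alone; median 0.68; adjusted p = 4.6e-08), among them Ndufa7 of complex I (1.53 ± 0.25) and Cox5a of complex IV (1.47 ± 0.31). Of 16 myelinating Schwann cell genes 10 fell and 0 rose (13 adjusted over the list alone; median -0.94; adjusted p = 5.3e-06). The myelin genes Mbp (-1.54 ± 0.24) and Cnp (-1.83 ± 0.19), the node of Ranvier gene Gldn (-1.91 ± 0.25) and the glial transcription factor gene Sox10 (-1.73 ± 0.18) were in this group.

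Genes of the list of ErbB and Ras pathways and tumour suppressors, called ErbB and Ras below, moved in both directions in BDIV. Of 23 tested members 8 fell and 1 rose (10 and 1 adjusted over the list alone; median -0.56; camera adjusted p = 0.0454). This list and the fibroblast, red cell, granulocyte and cell cycle lists each had adjusted p = 0.890 with an estimated correlation. The receptor genes Erbb3 (-1.68 ± 0.21) and Erbb2 (-1.19 ± 0.18) fell, while Nrg1, which encodes their neuronal ligand, rose (2.93 ± 0.41, limma adjusted p = 0.00773). Whole nerve was measured, so a different share of Schwann cells and neurons in the pools cannot be told apart from regulation within cells. Of 13 non-myelinating or immature Schwann cell genes 4 fell and 0 rose (4 and 1 adjusted over the list alone), among them the intermediate filament gene Nes (-1.82 ± 0.19), and the list did not pass camera (adjusted p = 0.243). Of 21 fibroblast and perineurium genes 11 fell and 0 rose (12 adjusted over the list alone; median -0.85; adjusted p = 4.32e-05), including the matrix genes Col5a1 (-1.77 ± 0.18), Sparc (-1.55 ± 0.20) and Lum (-1.23 ± 0.18). Blood genes were lower: 6 of 10 red cell genes fell (8 adjusted over the list alone; median -1.79; adjusted p = 0.000922), with Hbb-b1 at -2.82 ± 0.28, and 4 of 14 granulocyte and marrow genes fell (8 adjusted over the list alone; median -1.74; adjusted p = 0.00211), with the haptoglobin gene Hp at -2.21 ± 0.44. Of 25 cell cycle genes 4 fell (4 adjusted over the list alone; median -0.74; adjusted p = 0.0023), including the replication licensing genes Mcm6 (-1.14 ± 0.23) and Mcm2 (-0.87 ± 0.20) and the mitotic activator gene Cdc20 (-0.71 ± 0.18). The ErbB and Ras call was lost without the BDIV female (adjusted p = 0.0829), BDIX female (0.0991) or Mss4d male array (0.0611), without background correction (0.0686) or with detection on all 8 arrays required (0.117). The cell cycle call was lost without the BDIV male (0.104) or BDIX male array (0.114) or with detection on all 8 arrays required (0.0507), and the granulocyte call without the BDIV male array (0.0603).

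The largest rises in BDIV were Rpl30 (5.81 ± 0.30, limma adjusted p = 0.00034), which encodes a ribosomal protein, Plekhh1 (at least 21.8-fold), Tlcd3b (3.50 ± 0.23), Pafah1b1 (3.39 ± 0.24) and the class I histocompatibility gene RT1-CE16 (at least 7.43-fold). Gpx2, a glutathione peroxidase gene (3.15 ± 0.31), Reg3a (2.98 ± 0.30, detected on 1 of 2 BDIX arrays), Celf6 (2.96 ± 0.27) and the somatostatin gene Sst (2.91 ± 0.35) followed. The largest falls were Hba-a3 (-5.04 ± 0.38), Fam151b (at least 18.6-fold lower), the defensin gene Defa5 (-4.32 ± 1.04), the prolactin gene Prl (-4.18 ± 0.78), S100a8 (-4.10 ± 1.08) and Lgals5 (-4.00 ± 0.35). The lipoxygenase gene Alox15 (at least 9.98-fold lower), the erythroid genes Hemgn (at least 8.86-fold lower) and Alas2 (at least 7.0-fold lower), and Ifi47 (at least 5.18-fold lower) were next. Rpl30, the globin, defensin and RT1 genes belong to families of similar sequence, so a probe may read relatives. None of these largest rises and falls had another tested probe, so a sequence variant under the probe cannot be told apart from expression. Over 49 pairs, other probes of genes called in this comparison showed a median of 0.531 of the called difference (lower quartile 0.174), 43 with the same sign. Of 7 tested pituitary genes 2 rose and 1 fell, and that list did not pass camera (adjusted p = 0.982). The pituitary list did not pass in Mss4d against BDIX (0.196) or between the sexes (0.103) either, where Prl was also lower. Other tissue in the pools was not tested as a source of Prl.

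In all, 2758 probes passed in BDIV against BDIX, 1313 higher and 1445 lower. With arrays scaled to their medians 3258 passed and 62.5% of them were higher, against 47.6%. The count rested on single arrays: it was 14 without the BDIV female array, 55 without the BDIV male array, 30 without the BDIX female array and 2533 without the BDIX male array. Of 48 named genes past the threshold, 5 (Rpl30, RT1-CE16, Tlcd3b, Fam151b and Alox15) passed with each of the 8 arrays left out in turn.

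**Figure D1:**
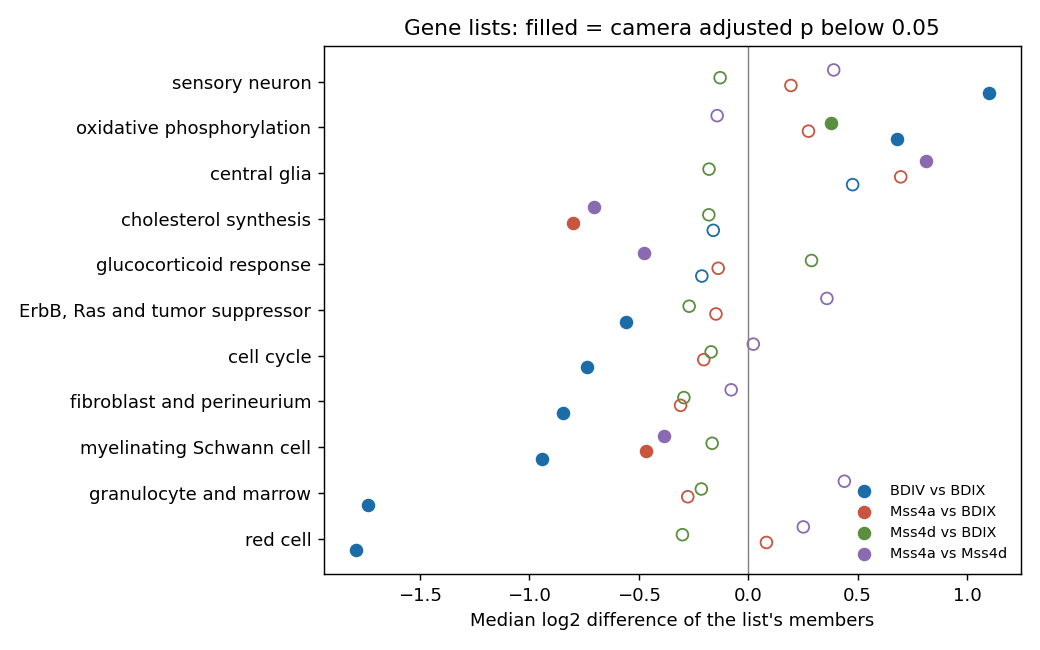
Median log2 difference of the tested members of each list that passed camera in at least 1 strain comparison, with a point per comparison and filled points past the threshold. The sensory neuron list stood at 1.10 in BDIV against BDIX and the red cell list at -1.79.

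Mss4a against BDIX asks what the BDIV segment of this congenic strain changes. Genes of cholesterol synthesis and of myelin were lower in Mss4a nerve. Of 17 tested cholesterol synthesis genes 9 fell and 0 rose (11 adjusted over the list alone; median -0.80; camera adjusted p = 6.11e-06), including Idi1 (-2.06 ± 0.18), Cyp51 (-1.92 ± 0.21), Fdps (-1.67 ± 0.22) and Dhcr7 (-1.03 ± 0.19), which act at successive stages of the pathway. This list and the myelinating Schwann cell list had adjusted p = 0.890 with an estimated correlation. Of 16 myelinating Schwann cell genes 6 fell and 0 rose (7 adjusted over the list alone; median -0.47; adjusted p = 0.00326): Mbp (-2.12 ± 0.24), Pllp (-1.82 ± 0.20), the galactolipid enzyme gene Ugt8 (-1.77 ± 0.21) and the myelin-associated glycoprotein gene Mag (-1.15 ± 0.27) were among them. The myelin call was lost with arrays scaled to their medians (adjusted p = 0.0611). Of 21 fibroblast and perineurium genes 4 fell and 2 rose (8 and 2 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0824). The collagen genes Col1a1 (-2.09 ± 0.30) and Col3a1 (-1.58 ± 0.22) fell, Fmod (2.35 ± 0.23) and Fbln1 (1.02 ± 0.19) rose, and Col1a2 (-0.17 ± 0.18) and Col5a1 (-0.51 ± 0.18) did not pass. Of 16 fatty acid and lipid synthesis genes 4 fell and 0 rose (5 adjusted over the list alone), Acly (-1.17 ± 0.18) and Fads1 (-1.38 ± 0.22) among them, and this list did not pass either (0.0526).

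The largest rises in Mss4a were the airway secretion gene Bpifa1 (at least 36.2-fold), the lipase gene Lipf (at least 16.2-fold), Vegp2 of the salivary von Ebner glands (at least 12.6-fold), the olfactory cytochrome gene Cyp2g1 (at least 8.79-fold), the lipocalin gene Lcn1 (3.39 ± 0.66) and the nasal cytochrome gene Cyp2a3 (at least 3.56-fold). Other tissue in the Mss4a pools was not tested as a source of these transcripts. Plekhh1 rose at least 20.9-fold, as in BDIV, and Fmod, Aplp1 (2.26 ± 0.31) and Slc39a12 (2.24 ± 0.51, detected on 1 of 2 BDIX arrays) completed the set. Plekhh1 and Gpx2 lie on chromosome 6 of the GRCr8 assembly. Gpx2 also rose in Mss4a, by 2.22. The largest falls were the cartilage genes Cnmd (-2.88 ± 0.20) and Epyc (-2.86 ± 0.42), the kinesin gene Kif5b (-2.46 ± 0.29), Tmprss5 (-2.36 ± 0.27), Bet1 (-2.33 ± 0.21), Purb (-2.31 ± 0.27) and Sh3bgrl1 (-2.21 ± 0.47). Cdc25b, a cell cycle phosphatase gene, fell at least 3.36-fold and the casein kinase gene Csnk1a1 at least 3.11-fold. Neurl2 fell by 2.36 with 1 probe, while its other probe stood at 1.20.

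In Mss4a against BDIX 1605 probes passed, 627 higher and 978 lower. The direction of the counts followed the scaling: 39.1% were higher here, 4.43% of 3994 with arrays scaled to their medians and 65.7% of 2028 with the authors' values, where the median of all probes shifted by -0.37 and 0.19. The count was 0 without the BDIX female array (3419 at unadjusted p under 0.05 in limma), 927 without the BDIX male array, 161 and 240 without the Mss4a female or male array, and 186 without either BDIV array. None of the 35 named genes past the threshold passed with every array left out in turn.

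Mss4d against BDIX asks the same for the other congenic strain. The largest rises were the thyroglobulin gene Tg (at least 328-fold) and Calca (at least 104-fold), which encodes calcitonin and the neuropeptide CGRP, and both were higher in the male than in the female pool. Tg stood at 12.20 in the female and 14.87 in the male array, against a mean of 5.01 in the 6 arrays of other strains. Of 15 thyroid genes with a probe, 14 were raised more than 2-fold in the Mss4d male array and 4 in the female array. Gpx2 (2.86 ± 0.31), Prr15 (2.24 ± 0.39), C1h19orf81 (2.02 ± 0.44), the histone deacetylase gene Hdac4 (1.96 ± 0.21), the thyroid hormone receptor gene Thrb (1.85 ± 0.39), Cdk14 (1.83 ± 0.31), Kcnj13 (at least 3.31-fold) and Tbx3 (1.80 ± 0.35) also rose. Plekhh1 was at 1.48 and did not pass (limma adjusted p = 0.207).

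Falls in Mss4d included the caveola genes Cav1 (-3.10 ± 0.36, other probe -2.60) and Cavin1 (-2.68 ± 0.42, detected on 1 of 2 Mss4d arrays), the creatine synthesis gene Gatm (-3.10 ± 0.31), Prl (-3.90 ± 0.78), Sh3bgrl1 (-3.20 ± 0.47), Cmtm6 (-2.74 ± 0.38), Tmprss5 (-2.74 ± 0.27), Tmx1 (-2.73 ± 0.27) and Zfp260 (-2.71 ± 0.27). The protease gene Adam10 fell at least 11.2-fold with 1 probe, and its other probe stood at -1.0. Of 16 myelinating Schwann cell genes 2 fell, Mbp (-2.12 ± 0.24) and Ugt8 (-1.08 ± 0.21), and the list did not pass camera (adjusted p = 0.325). The fatty acid elongase gene Elovl5 (-2.54 ± 0.27), the Schwann cell sodium channel gene Scn7a (-1.46 ± 0.21) and the tumour suppressor gene Rb1 (-1.67 ± 0.33) fell, each the 1 member of its list past limma over all genes. Adjusted over the list alone 4 fatty acid and lipid synthesis genes fell and 2 rose, and 3 non-myelinating or immature Schwann cell genes fell. Of the ErbB, Ras and tumour suppressor list 4 genes fell in the same way, Rb1 among them. None of these 3 lists passed camera (adjusted p = 0.348, 0.329 and 0.0772). Of 9 endothelial genes 2 rose and 0 fell, Tie1 (1.54 ± 0.22, other probe 0.50) and Egfl7 (1.02 ± 0.22). Adjusted over the list alone 4 rose and 1 fell, with Tek at -0.84 ± 0.24, and the list did not pass (adjusted p = 0.0517). Within Mss4d the median male minus female difference of these 9 genes was 0.53, with 7 higher in the male array. That array also held the most thyroid transcripts. The oxidative phosphorylation list was the 1 list past camera (45 genes, median 0.38, adjusted p = 0.00233, adjusted p = 0.919 with an estimated correlation), with 0 members past limma over all genes and 0 adjusted over the list alone. Its members Ndufb7 (1.23 ± 0.33) and Ndufa6 (0.95 ± 0.27) did not pass. That call was lost without the BDIX female array (adjusted p = 0.391) or the Mss4d female array (0.0763), and with the authors' values (0.0569).

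In Mss4d against BDIX 700 probes passed, 181 higher and 519 lower. The share of higher probes was 25.9%, but 71.9% of 2723 with arrays scaled to their medians and 45.8% of 679 with the authors' values, where the median of all probes shifted by 0.25 and 0.13. The count was 0 without the BDIX female array (2359 at unadjusted p under 0.05 in limma), 1177 without the BDIX male array, 4 without the Mss4d male array, 314 without the Mss4d female array and 40 without either BDIV array. None of the 27 named genes past the threshold passed with every array left out in turn.

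**Figure D2:**
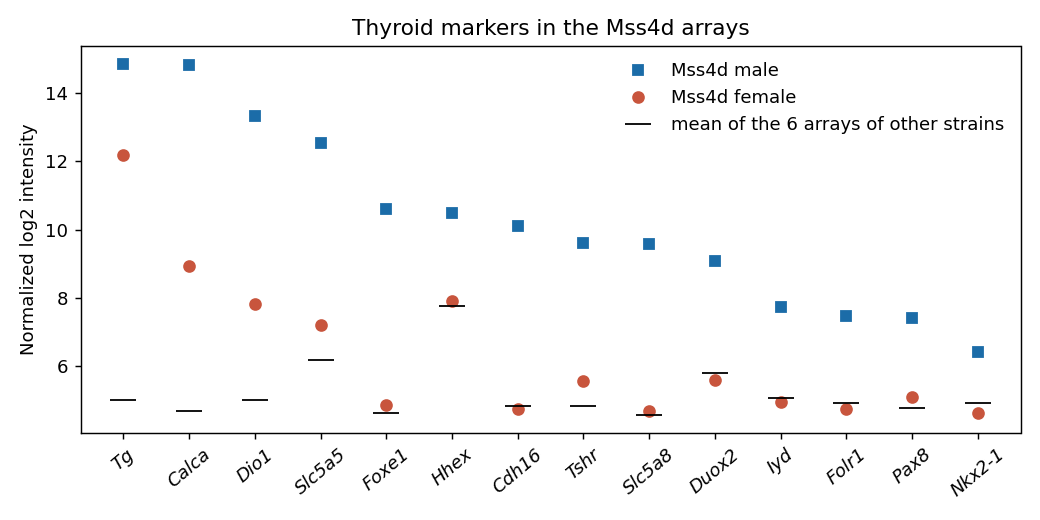
Normalized log2 intensity of 14 thyroid marker genes in the Mss4d male and female arrays, with a line at the mean of the 6 arrays of other strains. Of 15 genes with a probe, these 14 were plotted because they stood more than 2-fold above that line in the male array. Their place above it was therefore set by that choice. Slc26a4 (4.57 in the male array) was left out, and Tg reached 14.87 there.

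Mss4a against Mss4d compares the congenic strains directly. Cholesterol synthesis genes were lower in Mss4a than in Mss4d: of 17 genes 3 fell and 0 rose (8 adjusted over the list alone; median -0.70; camera adjusted p = 1.24e-06), namely Idi1 (-1.60 ± 0.17), Cyp51 (-1.35 ± 0.22) and Tm7sf2 (-1.31 ± 0.19, other probe -0.90). This list and the myelinating Schwann cell, central glia and glucocorticoid response lists each had adjusted p = 0.890 with an estimated correlation. Of 16 fatty acid and lipid synthesis genes 2 fell, Acly (-1.10 ± 0.18) and Fads2 (-1.30 ± 0.19), and Elovl5 rose (4 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.226). Of 16 myelinating Schwann cell genes 1 fell, Pllp (-1.28 ± 0.20), with 4 adjusted over the list alone (median -0.38; adjusted p = 0.00599). The central glia list was higher (12 genes, 0 past limma over all genes, 2 rose adjusted over the list alone, median 0.81, adjusted p = 0.00599), with Aqp4 at 1.92 ± 0.64 (detected on 1 of 2 Mss4d arrays) and Hapln2 at 0.96 ± 0.21, neither past the threshold. Hapln2 stood at -0.089 with arrays scaled to their medians. The glucocorticoid response list was lower (12 genes, 0 past over all genes, 3 fell adjusted over the list alone, median -0.47, adjusted p = 0.0348), with Klf9 at -1.10 ± 0.23 and Mt1 at -1.16 ± 0.34, neither past the threshold. The central glia call was lost without the Mss4a female array (adjusted p = 0.147) and the glucocorticoid call without the Mss4a male (0.203) or the Mss4d male array (0.525). Detection on all 8 arrays required ended the glucocorticoid call (0.117), as did arrays scaled to their medians (0.274), which also ended the myelin call (0.0919), and the authors' values ended the myelin call (0.122).

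Single genes higher in Mss4a than in Mss4d were Lipf (at least 15.2-fold), Cyp2g1 (at least 8.24-fold), Cyp2a3 (at least 3.34-fold), Cyp2f4 (at least 3.21-fold), Slc6a20a (2.23 ± 0.26), Synpr (2.07 ± 0.27), Elovl5 (1.88 ± 0.27), Ptbp2 (1.72 ± 0.27), Stom (1.63 ± 0.27) and the muscle genes Tnnc2 (2.03 ± 0.29) and Mb (at least 1.98-fold). Lower were Tg (at least 272-fold), Lims1 (-3.09 ± 0.37), Tmtc3 (at least 3.53-fold), Tbx3 (-2.30 ± 0.34), Clic5 (at least 3.37-fold), Retreg3 (-2.12 ± 0.21), Bbs4 (-2.08 ± 0.25), Lipogenin (-2.01 ± 0.20), Rpl30 (at least 3.14-fold) and the copper transporter gene Atp7a (at least 2.62-fold). Lims1, Tbx3 and Lipogenin were detected on 1 of 2 Mss4a arrays. Of 10 cartilage and bone genes 2 fell and 0 rose (4 and 0 adjusted over the list alone), Cnmd (-1.71 ± 0.20) and Col2a1 (-1.60 ± 0.19). Of 14 skeletal muscle genes 2 rose, Tnnc2 and Mb, and 0 fell (4 and 1 adjusted over the list alone), and neither list passed camera (adjusted p = 0.103 and 0.171). In all 160 probes passed, 39 higher and 121 lower. The share of higher probes was 24.4%, but 1.77% of 6669 with arrays scaled to their medians, where the median of all probes shifted by -0.65, and 13.6% of 22 with the authors' values. The count was 0 without either BDIV array (2432 at unadjusted p under 0.05 in limma), 37 without either BDIX array, 23 and 25 without the Mss4a female or male array, 252 without the Mss4d female array and 6 without the Mss4d male array. Of 29 named genes past the threshold, 6 lost their call whichever array was left out, and none passed with every array left out in turn.

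**Figure D3:**
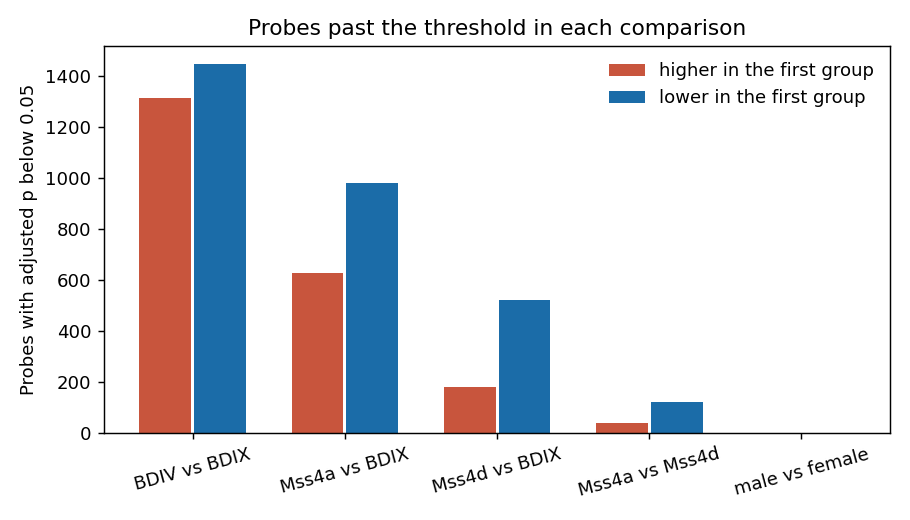
Probes with a limma adjusted p below 0.05 in each comparison, by direction. The counts run from 2758 in BDIV against BDIX to 0 between the sexes.

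**Figure D4:**
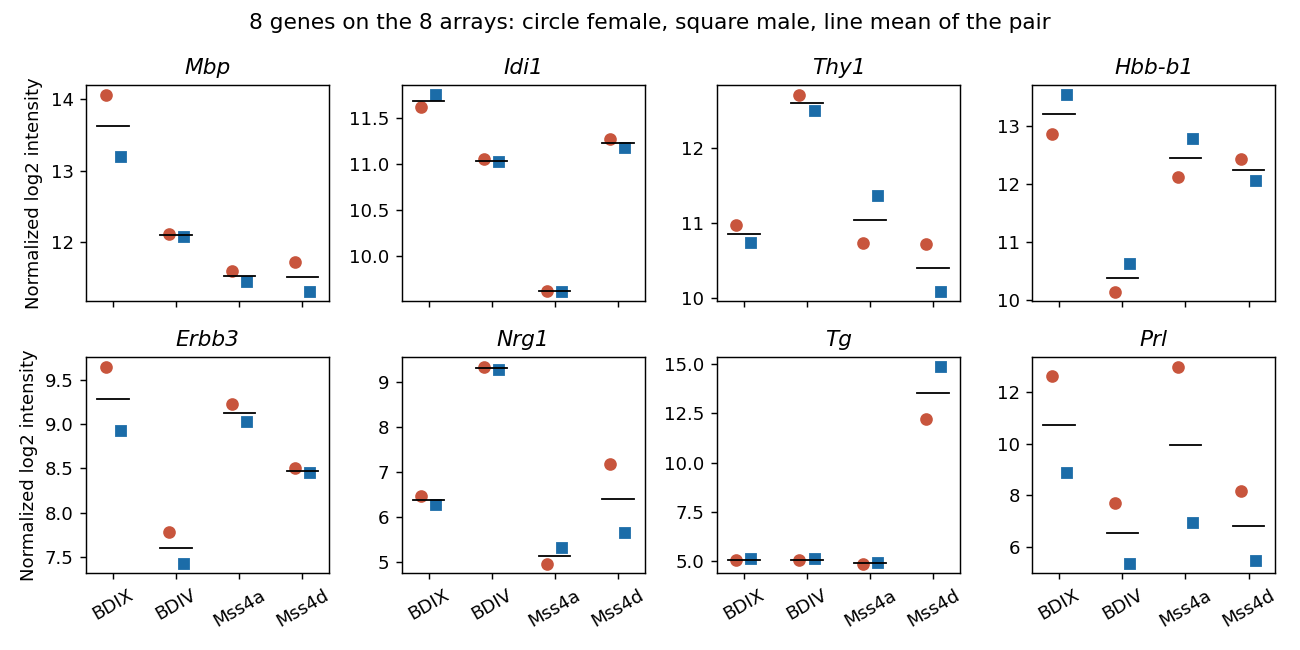
Normalized log2 intensity of 8 genes on the 8 arrays, with circles for female pools, squares for male pools and a line at the mean of each pair. Mbp lay above 13 on both BDIX arrays and below the BDIX level in the other strains, and Tg lay near 5 on the 6 arrays outside Mss4d.

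A congenic strain differs from its recipient by a donor segment, so calls were counted by chromosome over 9138 tested genes placed in the GRCr8 assembly. No chromosome passed Fisher's exact test after adjustment over 84 tests. The nearest was chromosome 3 in Mss4a against BDIX, with 107 of 685 genes called (15.6%) against 11.3% elsewhere (exact p = 0.00124, adjusted p = 0.104). On chromosome 6, 48 of 384 genes were called in Mss4a (12.5%) against 11.6% elsewhere, and 25 of 384 in Mss4d (6.51%) against 4.90%. Calls lay on 21 chromosomes in each comparison with BDIX. The richest windows of 20 neighbouring genes held 8 called genes in Mss4a and 5 in Mss4d, with permutation p = 0.932 and 0.979. Each maximum was reached on 2 chromosomes, for example between Aplnr and Fnbp4 in Mss4a and between Tfrc and Cldn1 in Mss4d.

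Direction in the congenic strains was compared with that in BDIV. Of the probes called in Mss4a, 64.4% had the sign of the BDIV difference, and 71.1% of those called in Mss4d did. Simulated groups without any change that shared the BDIX arrays gave a mean of 84.3% and 87.0%, and real changes unrelated to BDIV would lower these shares. Without the BDIX male array the shares were 86.1% and 89.8%, where simulations with that array left out gave a mean of 95.3% and 94.9%. The covariance with the BDIV difference lay above the simulations, at 0.108 in Mss4a (highest simulated 0.0548) and 0.103 in Mss4d (0.0584). The simulations gave every array the same spread, while the BDIX pair differed most (SD 0.525 against 0.200 in BDIV). A larger spread of the shared BDIX arrays alone would raise the covariance, so it cannot decide whether changes are shared with BDIV. The correlation lay below the simulations, at 0.246 in Mss4a (lowest simulated 0.463) and 0.236 in Mss4d (0.454). Real changes unrelated to BDIV would lower the correlation too. With the congenic difference taken in 1 sex and the BDIV difference in the other, so that no array was shared, the correlations across probes were 0.0656 and 0.0865 for Mss4a and 0.0757 and 0.0822 for Mss4d. BDIV minus BDIX and Mss4a minus Mss4d correlated with r = 0.010 and rho = 0.022, a contrast in which changes common to both congenic strains cancel.

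Mss4a and Mss4d shared 77 higher and 268 lower probes against BDIX, where independent lists would share 8.65 and 38.7. Both use the BDIX arrays, and with that built in the simulated correlation between them averaged 0.498 (highest 0.527) against 0.577 observed, and the highest simulated covariance was 0.0558 against 0.215. The simulations hold independent array noise of the same spread on every array. A batch common to both BDIX arrays, or a larger spread of the BDIX arrays, is therefore not covered by them.

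Between the sexes, 9 lists, granulocyte and marrow, cell cycle and class I presentation among them, were higher in males and the central glia and X-linked lists in females, with strains adjusted for, but no single probe passed. Each of the 11 lists that passed camera had adjusted p = 0.890 with an estimated correlation. Splits of the arrays other than by sex called between 5 and 13 lists at the preset correlation. The granulocyte and marrow list had a median of 1.04 over 14 genes (camera adjusted p = 7.0e-10), with Defa5, detected on all 8 arrays, at 1.99 ± 0.73. The cell cycle list followed with 0.48 over 25 genes (adjusted p = 4.6e-08), with Cks2 at 1.09 ± 0.34 and Cdc20 at 0.51 ± 0.13. The class I presentation list had a median of 0.34 (adjusted p = 5.13e-06), oxidative phosphorylation 0.20 (5.3e-06), red cell 0.26 (0.00292), T and NK cell 0.19 (0.00772), adipocyte 0.33 (0.0261), complement 0.22 (0.0298) and mast cell 0.42 (0.0454). The interferon response (adjusted p = 0.143), macrophage (0.175) and class II presentation lists (0.214) did not pass. The central glia list had a median of -0.39 (adjusted p = 0.000187), with the water channel gene Aqp4, detected on 3 of 4 male arrays, at -1.11 ± 0.45. The X-linked list, of genes that escape inactivation, had a median of -0.30 over 4 genes (adjusted p = 0.00169): Eif2s3 was at -0.82 ± 0.15, Usp9x at -0.39 ± 0.14 and Ddx3x at -0.20 ± 0.14, lower in males in all 4 strains. Over all genes 0 members of these 11 lists passed limma, and adjusted over the list alone 1 central glia and 1 X-linked gene fell.

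The values of the sex difference varied between strains. The marrow list was higher in males by 1.44 in BDIX and 2.79 in Mss4a but 0.05 in BDIV and 0.03 in Mss4d, and the cell cycle list by 0.80, 0.63, -0.01 and 0.15 in the same order. These values rest on 1 array each and were not tested within a strain. The red cell call was lost without either Mss4a array (adjusted p = 0.279 and 0.253), the oxidative phosphorylation call without either BDIX array (0.144 and 0.146) and the adipocyte call without either Mss4d array (0.112 and 0.159). The mast cell call was lost without either Mss4a (0.0722 and 0.0642) or Mss4d array (0.597 and 0.631), the complement call without either Mss4d array (0.0976 and 0.139), and without either BDIX array the complement and T and NK cell medians turned to -0.018 and -0.0049. The authors' values ended the adipocyte (0.0645) and mast cell calls (0.135), no background correction the mast cell call (0.0686), no filter the adipocyte call (0.0556), and detection on all 8 arrays the adipocyte (0.0515) and T and NK cell calls (0.295).

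Of single genes, 0 passed limma between males and females, where 526 had an unadjusted p under 0.05 and 655.7 would by chance. The smallest p-values belonged to the chemokine gene Cxcl13 (1.02 ± 0.15), Syk (0.76 ± 0.17), Slfn4 (0.77 ± 0.18), Mmp23 (0.73 ± 0.17) and Pkmyt1 (0.53 ± 0.13) among genes higher in males, the last 2 detected on 3 of 4 female arrays. Lower in males were Prl (-3.70 ± 0.55), Eif2s3, Coch (-0.85 ± 0.17), Cldn11 (-0.93 ± 0.19) and Gem (-0.75 ± 0.16). Each had adjusted p = 0.926 and the same sign in all 4 strains. Of 16 Y-linked genes 0 were tested, and Xist was not analysed here.

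**Figure D5:**
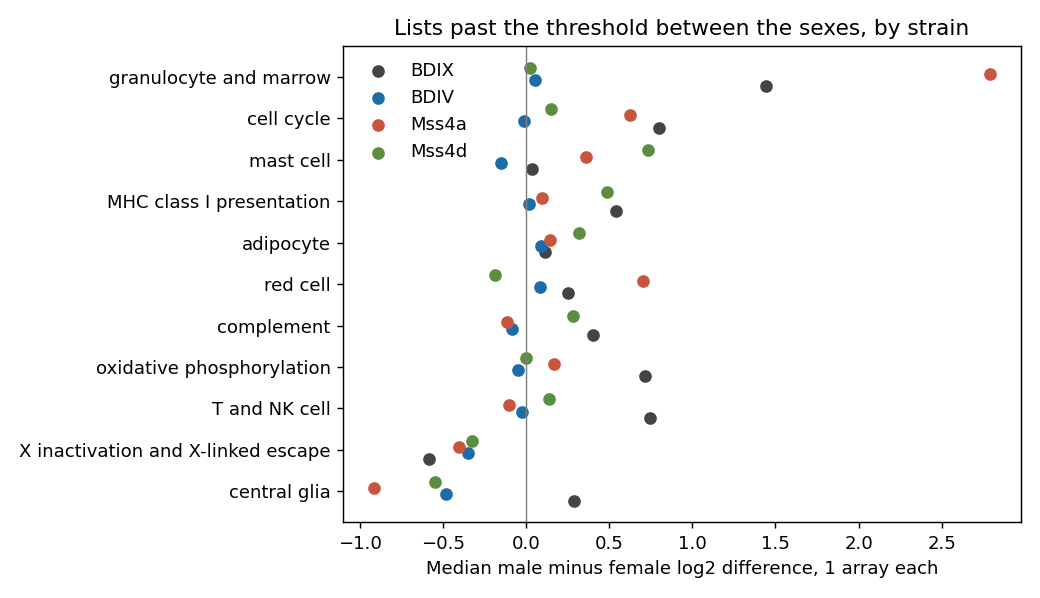
Median male minus female log2 difference of the 11 lists past camera between the sexes, with a point per strain from 1 array of each sex. The granulocyte and marrow list reached 2.79 in Mss4a and 0.03 in Mss4d.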

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

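The tests of other probes of the same gene, of marrow precursor genes and of other splits of the arrays were chosen before their results were seen, and the tests of thyroid markers, chromosome shares, array brightness and equal effects over sexes or strains, Dixon's test of the 5 genes with the widest range, and the count of distinct fits among the splits, only after.

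Differences between male and female arrays that ran in opposite directions in different strains drew attention to 5 genes and 2 lists, each from 1 array per strain and sex, so that the difference between strains was not tested. The range over strains of male minus female was 6.42 for Pon3, 6.27 for Epcam, 5.89 for Slc5a5 and 5.62 for Plvap, with the highest value in Mss4d in each. For Klk6 it was 5.72, from 2.62 in BDIX to -3.10 in Mss4a. The median of the central glia list ranged over 1.20, from 0.29 in BDIX to -0.91 in Mss4a, and that of the oxidative phosphorylation list over 0.763, from 0.71 in BDIX to -0.05 in BDIV. In Dixon's test, run on the 4 arrays of each sex for array brightness, detected probes, the 10 named sex genes and these 5 genes, the Mss4d male array stood apart for Pon3 (gap over range 0.849) and Plvap (0.835). Chance flags about 1 in 20 groups, a rate that does not hold for these 5 genes, which were chosen for their range. Of the 4 groups of brightness and detected probes 0 were flagged.

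Thyroid transcripts were high in the Mss4d pools, with Tg at 12.20 and 14.87 in the female and male arrays. A donor segment acting in cis is argued against by the 7 chromosomes of GRCr8 that hold the raised markers, and a strain effect of the same size in both sexes by their median male minus female difference of 3.78, where the other strains lay between -0.06 and 0.02 (3.51 over the 3 markers detected in other strains, which lay there between -0.35 and 0.05). Thyroid tissue in the RNA of the Mss4d male pool may account for the pattern there: the 11 markers other than Tg, Calca, Pax8 and Slc26a4 had a median 4.78 above the arrays of other strains (4.04 over 10 without Slc5a5, already named for its range), with Dio1 at 13.32 and Slc5a5 at 12.54, while 2 to 4 of the 15 markers were detected in each array of other strains. In the female pool Tg reached 15.6% of the male signal above background but Calca 1.58%, Dio1 1.89% and Tshr 2.44%, and thyroid tissue there was not tested separately. A strain effect in males alone stays open and was not tested.

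Differences of the congenic strains from BDIX were spread over all chromosomes. A donor segment acting in cis is argued against as the whole cause, since the chromosome with the most calls held 12.1% of them in Mss4a and 10.6% in Mss4d, and 12.7% of tested genes. Array brightness that follows strain cannot be told apart from strain, because in 4 of 4 strains the 75th percentile of signal was closest between the strain's own arrays. A donor sequence variant under the probe would lie in the donor segment, so as the whole cause the same shares argue against it. For part of the calls such a variant cannot be told apart: other probes of called genes showed a median of 0.0903 of the called difference in Mss4d (15 pairs) but 0.525 in Mss4a (26 pairs), too few and too uneven to decide. A donor effect acting in trans stays open and was not tested.

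The marrow and cell cycle lists were higher in males. A sex effect of the same size in every strain cannot be told apart from an uneven one: the marrow list median was 0.0543 in BDIV and 0.03 in Mss4d, where the mean over strains was 1.08 with an SD of 1.32, and each value rests on 1 array of each sex. Marrow cells in the BDIX and Mss4a male pools may contribute but were not settled: 4 precursor genes outside the fixed lists, detected in at least 2 of the other 6 arrays, had a median male minus female difference of 0.946 in BDIX and 1.83 in Mss4a (Vpreb3 -0.09), against 0.0053 in BDIV and -0.041 in Mss4d. The BDIX and Mss4a medians both passed the limit set for marrow cells beforehand. A check over all 12 with a probe, most of them near background, was not part of that plan. There the medians were 0.11 in BDIX and -0.03 in Mss4a, so too few detected genes keep this open. A sex effect that differs between strains stays open and was not tested.

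Other splits of the 8 arrays into 4 and 4, with strain as a term, gave 32 fits of 35, of which 20 were distinct, too few for a share under 0.05. For probes between the sexes the real split gave 0, so that 20 of 20 splits necessarily gave as many, and the highest other gave 3. For lists the real split gave 11, and 2 of 20 gave as many. The highest other gave 13, in a split that parts the pairs of 2 strains and so compares 4 arrays, as 12 of the 20 do. No split gave fewer than 5 lists, so groupings other than by sex also called lists at the preset correlation. Among the 8 splits that part every strain's pair the real one gave 11 and the highest other 9.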

How the results depend on the processing

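The alternatives without both Mss4d arrays, without each strain in the sex lists, and without each array for lists, chromosomes and donor direction were chosen after seeing the data; the others were planned. Probes called between the sexes stayed at 0 in every alternative run, with 43 to 866 at an unadjusted p under 0.05 in limma.

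Without background correction 88 probes passed in Mss4a against Mss4d, 2 lists passed in Mss4d against BDIX, and the share with the BDIV sign was 67.2% in Mss4a and 66.4% in Mss4d. With arrays scaled to their medians 3994 probes passed in Mss4a against BDIX, 2723 in Mss4d against BDIX and 6669 in Mss4a against Mss4d, with 4, 3 and 7 lists, and Hapln2 turned to -0.089 in Mss4a against Mss4d. The authors' values gave 22 probes in Mss4a against Mss4d. With no filter 303 probes passed in Mss4d against BDIX and 21 in Mss4a against Mss4d, 4 lists in Mss4a and 5 in Mss4d against BDIX, and 1 chromosome in BDIV against BDIX (adjusted p = 0.0405). With detection on all 8 arrays 249 probes passed in Mss4a against Mss4d and 5 lists in BDIV against BDIX. With no moderation the counts were 46 in BDIV, 6 in Mss4a and 0 in Mss4d against BDIX and 0 in Mss4a against Mss4d, where 2584 and 2406 probes had an unadjusted p under 0.05. With no sex term 258 probes passed in Mss4a against Mss4d. With only the 4 arrays of the strains compared 110 passed in Mss4d against BDIX and 0 in Mss4a against Mss4d (2352 at unadjusted p under 0.05 in limma). Without both Mss4d arrays 4 lists passed in Mss4a against BDIX. With an estimated correlation 0 lists passed in each of the 5 comparisons. On simulated data that test also missed a planted shift of 0.5 in the oxidative phosphorylation list (camera adjusted p = 0.283), which the preset correlation found. The simulated genes varied independently, while this list had an estimated correlation of 0.345 in the data. That simulation therefore cannot tell which correlation is right here. Without the BDIX pair the complement median was -0.018 and the T and NK cell median -0.0049 between the sexes. The cause was not tested, except that fits without moderation or with fewer arrays have fewer degrees of freedom. That cannot explain why the counts against BDIX differed between leaving out the BDIX female and the BDIX male array. Both of those fits have 2 residual degrees of freedom, so that gap came from the values of the BDIX array that was kept.

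Leaving out 1 array in turn gave from 14 to 2781 probes in BDIV, 0 to 1241 in Mss4a and 0 to 1177 in Mss4d against BDIX, 0 to 252 in Mss4a against Mss4d and 0 to 0 between the sexes. Lists ranged from 6 to 11, 2 to 11, 1 to 10, 4 to 8 and 8 to 14 in the same order, and chromosomes past the threshold were 0 throughout in the 4 strain comparisons. The share with the BDIV sign ranged from 66.6% to 86.1% in Mss4a and 50% to 89.8% in Mss4d, where the 50% rests on 4 called probes without the Mss4d male array, and the correlation without shared arrays from -0.084 to 0.083. The complement median between the sexes ranged from -0.018 to 0.329 and the T and NK cell median from -0.0049 to 0.305. The fit without the BDIX female array called 0 probes in both congenic strains and gave no share. Of 1296 gene values with an array left out 790 kept their side of the threshold and direction, 504 were no longer past it, 2 newly passed and 0 reversed. Of 162 named values 48 in BDIV, 35 in Mss4a and 27 in Mss4d against BDIX were past the threshold, and 29 in Mss4a against Mss4d. The others had no call to lose and, unless they newly passed, count above as kept. No moderation ended 133 of the calls, no filter 48, the authors' values 33 and no background correction 29. The trended robust variance ended 6 and median scaling 2, which also let 5 newly pass. Among the 145 strain values, only the 4 arrays of the strains compared ended 41 calls and no sex term 13. Without a strain term 0 of the 17 sex values newly passed, and these had no call to lose. Of 96 left with detection on all 8 arrays 0 ended and 1 newly passed. Signal over background limits the dim genes, whose folds are lower bounds.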

Other observations

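All lists named below as added were written after the data were examined, and their values were not tested.

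In BDIV against BDIX the clock genes Nr1d1 (-2.12 ± 0.22) and Bmal1 (-1.08 ± 0.17) and the immediate early genes Egr1 (-1.54 ± 0.18) and Fos (-1.33 ± 0.34) fell. Of 13 circadian clock genes 3 fell (3 adjusted over the list alone) and of 23 immediate early and stress genes 4 fell (3 adjusted over the list alone), and neither list passed camera (adjusted p = 0.0796 and 0.175). Of 23 interferon response genes 3 rose and 1 fell, with Mx2 at 1.88 ± 0.17 and Gbp2 at -1.01 ± 0.23. Of 18 class I presentation genes 3 rose and 1 fell, with RT1-A3 at 2.22 ± 0.24 and RT1-N3 at -0.92 ± 0.26. Of 9 endothelial genes 3 fell, with Vwf at -1.96 ± 0.18. The counts were the same adjusted over each list alone, and none of these 3 lists passed camera (adjusted p = 0.125, 0.325 and 0.203). Without an array of BDIV or the BDIX female array most calls of this comparison were lost, and 14 probes passed without the BDIV female array.

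In Mss4a against BDIX the skeletal muscle genes Tnnc2 (1.97 ± 0.29), Acta1 (1.90 ± 0.47) and Mb (at least 2.11-fold) rose, 3 of 14 members over all genes (6 rose and 1 fell adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0585). An added olfactory mucosa list had medians of 0.05 and 0.23 in the Mss4a female and male arrays against the arrays of other strains, with 4 and 5 of 17 genes raised more than 2-fold. Cyp2a3 and Cyp2g1 are among these in both arrays and S100a5 in the male, and they were noticed before the list was written. Over the 14 other genes the medians were 0.015 and 0.14. Of the 17 genes 11 were detected in at least 1 array. An added epithelium list had a median of 2.52 in the Mss4d male array, with 12 of 15 genes raised more than 2-fold, and 0.02 in the Mss4d female array. Over the 11 genes not noticed before that list was written, the medians were 2.49 and 0.02. All 15 epithelium genes were detected in at least 1 array, and between 10 and 12 of them in each array outside the Mss4d male. The B and plasma cell list had 2 tested members and was not tested.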
